A study of Mus musculus with 8 samples.

How the data were processed

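Live CD45+ CD8+ cells were sorted from tumours of female mice 6 days after radiotherapy, per the labels, which number the strain from C57BL/6 to C57BL/12 over the libraries. The 8 libraries form 4 groups of 2: irradiated (RT), untreated (UNTR), and the same 2 arms in mice given FTY720 (RT_FTY and UNTR_FTY), a drug given to block lymphocyte infiltration. The replicate is the library, and the labels give 8 mice for each group and 7 for UNTR_FTY. Per the labels, conditions with and without FTY720 were sequenced at different times.

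The deposited values are raw integer counts per feature and cell from BD Rhapsody libraries, and the authors' normalisation, if any, is not in them. The submitters' processing notes name the build mm39 and no aligner, so whether the counts are molecules or reads is not stated, and no coordinates are given. Per the file headers, the 2 runs hold different assays, although the protocol in the labels names a whole transcriptome kit for all libraries. The conflict is not resolved here. The libraries with FTY720 list 31610 genes over the run plus 8 antibody features. Those without FTY720 hold a panel of 394 genes, of which 387 had the same name in the other run, 5 were matched through an older or newer symbol and 2 were not matched. In all 8 libraries, 359 genes were listed. The effect of FTY720 itself was not fitted, because the drug and the assay changed together and the panel covers 1.24% of the genes of the other run.

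Cells with at least 200 detected genes (whole transcriptome) or 20 (panel) and a mitochondrial share of at most 25% were kept. Each run was clustered on its own with scanpy 1.11.5 (30 principal components, 15 neighbours, Leiden resolution 1.0, seed 0, with 2000 variable genes in the whole-transcriptome run, T cell receptor and antibody segments and mitochondrial genes left out). Clusters were named from marker sets fixed before the data were examined, only where at least 3 markers were raised and a marker was among the 10 leading genes. A cluster was taken as a T cell cluster where its Cd3e level was at least 50% of the median over clusters and it was not named for another lineage. The thresholds of both rules were chosen after the data were seen. Scrublet's automatic threshold marked at most 0.1% of the cells in 7 libraries and 2.54% in UNTR_FTY replicate 2, so it did not work as a doublet filter. No doublets were removed, and removal of the cells with the highest doublet scores, up to an expected 6% of each library, was added as an alternative.

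Counts were summed per library over all kept cells, over T cell clusters, and over classes with at least 50 cells in each library. RT was compared with UNTR within each run by edgeR 4.0.16 quasi-likelihood tests (TMM scaling, its filter on low counts, robust dispersion, Benjamini-Hochberg adjusted p under 0.05). The pooled fit used the genes listed in all 8 libraries with the run as a term, and the interaction the same genes with a mean per group. Standard errors (SE) of log2 fold changes come from the test's F statistic. Gene lists (25, fixed before the data were examined) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 where at least 4 members were measured, then with an estimated correlation and with fry. With an estimated correlation, camera uses the residual degrees of freedom, which are few with so few libraries. A list that fails it is thus not shown to be unchanged. Class shares were compared by two-sided exact permutation tests. With 2 libraries against 2, the smallest p such a test can give is 0.333, and 0.056 when arrangements are made within each run. Shares of cells with a count were also taken after thinning to 60 counts per cell in the panel run. Cells with fewer counts were left out of these thinned shares. GC content was computed from GENCODE transcript sequences for genes of a CPM of at least 20.

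Named genes followed a rule fixed before the data were examined: up to 10 genes per direction with the largest fold change among those past the threshold with both RT libraries on one side of both UNTR libraries, the smallest p where fewer than 5 passed, a set of anchor genes, and up to 4 members of each list. T cell receptor segments and predicted genes were left out. The tests were run on simulated counts made from the real means and dispersions with 200 changed genes. For RT without FTY720 (359 genes), 24% of genes changed 2-fold and 78% of those changed 4-fold were recovered. With FTY720 (22542 genes) the shares were 0% and 0% for edgeR, and 7% and 53% for DESeq2 1.42.0, which also made 66 false calls. The pooled fit recovered 58% and 94%, with 3 false calls among 159 unchanged genes, and the interaction 2% and 30%. The 200 changed genes were most of the 359 but few of the 22542. Recovery after adjustment depends on that share, so these values cannot be compared between the runs and may differ in the real data. In simulated lists, camera called 5 of 5 changed lists in each run and 2 of 15 unchanged ones without FTY720. The simulated genes were drawn independently of each other, so this does not cover lists of correlated genes. Macrophage genes, for example, had an estimated correlation of 0.943 in T cell clusters without FTY720.

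Alternatives were DESeq2's size factors and Wald test, no filter on low counts, other cell filters and cell sets, thinned libraries, other clusterings, each library left out in turn, and the replicate number as a block. Those on T cell clusters, the highest doublet scores, T cells as denominator, a GC content correction and T cells without the stem-like and naive-like cells of resolution 1.5 were added after the data were seen.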

Results

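CD45+ CD8+ cells sorted from mouse tumours 6 days after radiotherapy were profiled as single cells in 8 libraries, 2 for each of 4 groups: RT, UNTR, RT_FTY and UNTR_FTY. Per the labels FTY720 was given to block lymphocyte infiltration, and how complete the block was is not measured here. The libraries without FTY720 held between 9439 and 19012 kept cells and totals from 1939788 to 3950089 counts, with a median of 117 to 161 counts per cell over a targeted panel. Those with FTY720 held between 6296 and 8648 cells and totals from 55162470 to 157460711 counts, with a median of 5884 to 15119 gene counts per cell over the whole transcriptome. In UNTR_FTY replicate 1 the median mitochondrial share was 0.315%, against 4.53% to 4.87% in the other libraries of that run. Its nuclear genes also followed GC content: in T cell clusters the log2 ratio to the other libraries went from a median of -0.789 in the tenth of genes lowest in GC to 0.372 in the highest.

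The first comparison asks which CD8 T cell states differed after irradiation in mice without FTY720. Stem-like cells, led by Tcf7 and Ccr7, were 7.96% ± 1.41 of the cells (SD, n = 2) in RT and 29.58% ± 11.24 in UNTR, with both RT libraries below both UNTR libraries. Cycling-like cells (cluster 8, led by Mki67 and Top2a among others, and cluster 5, led by the replication genes Mcm2 and Mcm4) were 23.82% ± 16.42 in RT and 10.14% ± 3.76 in UNTR, and these libraries overlapped. Macrophage-like cells, which the CD8 sort should remove, were 0.84% ± 0.02 in RT and 12.81% ± 2.92 in UNTR. All clusters named for another lineage than CD8 T cells or low in Cd3e together made up 1.77% ± 0.28 and 21.16% ± 0.72, including CD4 or Treg-like T cells with 0.67% ± 0.37 and 0.25% ± 0.09. Exhausted-like cells were 48.35% ± 17.56 in RT and 28.03% ± 9.45 in UNTR, but at other clustering settings this difference of 20.32 percentage points was -3.04 (Leiden resolution 0.5), 1.44 (resolution 1.5) and -2.27 (cell cycle genes left out). The lower stem-like share also depended on the clustering: at Leiden resolution 1.5 the difference was -0.53 percentage points. There a cluster led by Tcf7 and Ccr7 was named naive-like, with 3.99% ± 0.10 in RT and 15.91% ± 7.96 in UNTR, and a cluster led by Xcl1 and Ccr7 was named stem-like. At resolution 0.5 no cluster was named stem-like. The exact permutation p was 0.333 for the stem-like, exhausted-like and macrophage-like shares, the smallest that 2 libraries against 2 can give, and 0.667 for the cycling-like share.

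**Figure D1:**
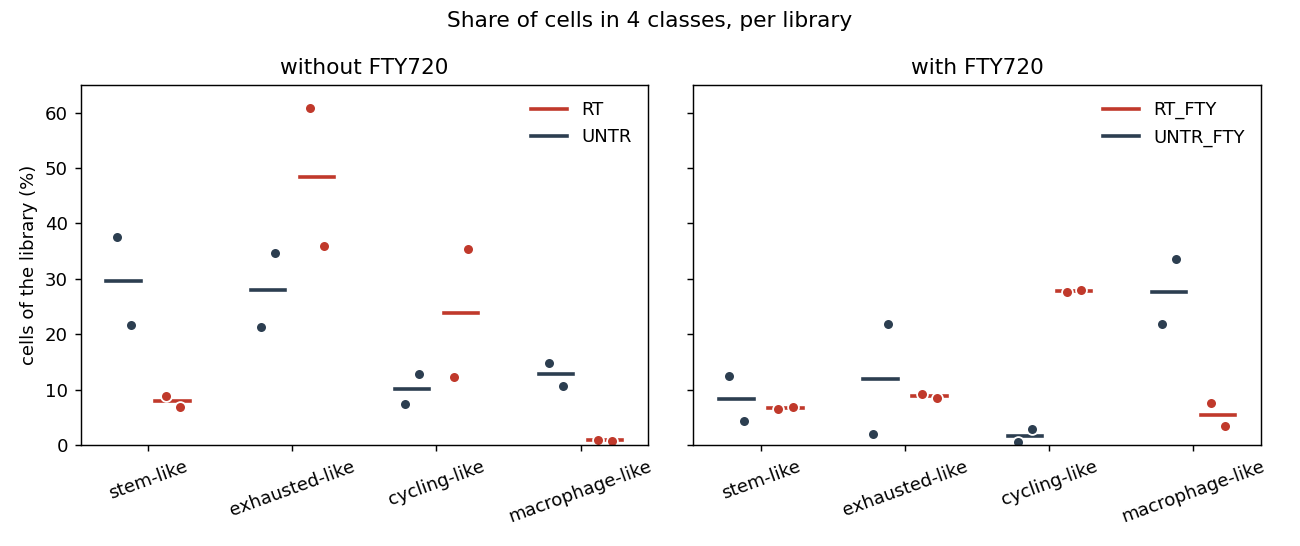
The share of a library's cells (%, y axis) is plotted for 4 classes (x axis) without FTY720 (left) and with it (right); each point is 1 library and each bar the mean of 2. Cycling-like cells were 27.79% in RT_FTY and 1.71% in UNTR_FTY on average (30.30% and 7.82% at resolution 0.5), and stem-like cells 7.96% in RT and 29.58% in UNTR.

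Within T cell clusters without FTY720, Klrg1, a receptor of effector T cells, rose by a log2 fold change of 3.67 ± 0.38 (SE, n = 2 libraries per group, edgeR adjusted p = 0.00339), or 12.7-fold. Rora (1.76 ± 0.20), Il12rb2, a chain of the interleukin 12 receptor (1.44 ± 0.17), and the chemokine receptor Ccr2 (1.46 ± 0.24) also rose. Bcl2, which protects cells from apoptosis, was 7.07-fold lower (-2.82 ± 0.26, adjusted p = 0.00237). Bcl2 is named for its values, outside the rule for named genes. Ccr7, a lymph node homing receptor, fell by 1.64 ± 0.36 on the log2 scale, and Tcf7, a transcription factor of quiescent T cells, by 1.57 ± 0.36. Xcl1, a chemokine that attracts dendritic cells, fell by 2.32 ± 0.40. Havcr2 (TIM-3), an inhibitory receptor, rose by 1.21 ± 0.34, and Gzmb, a granzyme, had a value of -0.12 ± 0.14 (adjusted p = 0.51). In these clusters 114 of 343 genes passed, 31 higher and 83 lower, and over all cells 205 of 359 passed, 86 higher and 119 lower. Over all cells Gzmb passed as higher (0.84 ± 0.27), so its sign turned with the cells summed. The lower genes in T cell clusters included macrophage genes such as C1qa (-4.38 ± 0.39) and C1qb (-4.03 ± 0.29), which macrophage-like cells, rarer in RT, express. Without RT replicate 1 the count in T cell clusters was 61, and without RT replicate 2 it was 40, against 130 and 131 over all cells. Without these libraries in turn, Tcf7 (adjusted p = 0.0787 and 0.0812), Havcr2 (0.14 and 0.0619) and Xcl1 (0.162 without RT replicate 1) no longer passed, and Ccr7 did not without RT replicate 1 (0.0806).

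Among the fixed lists in T cell clusters without FTY720, 5 of 10 measured stem-like genes passed as lower and 1 as higher, both over all genes and adjusted over the list alone. The list as a whole did not pass (adjusted p = 0.708). For exhausted CD8 T genes, 2 of 11 passed as higher, Havcr2 and Tigit, and 0 adjusted over the list alone. Over all cells the exhausted list passed as higher, with 6 of 11 genes past the threshold (camera adjusted p = 0.00622), but with an estimated correlation its adjusted p = 0.531. All 7 measured macrophage genes passed as lower in T cell clusters (camera adjusted p = 0.000354), and with an estimated correlation the adjusted p = 0.837. Thinned to 60 counts per cell, Tcf7 was seen in 3.25% and 3.26% of T cells with at least 60 counts in RT and 13.1% and 6.38% in UNTR. Unthinned and over all T cells these were 5.77%, 5.77%, 20.42% and 10.76%, at median depths of 152, 160, 103 and 116. Macrophage-like cells, which should lack Tcf7, showed it in 0.6% of cells in both UNTR libraries after thinning, and unthinned in 4.63% and 3.99% at median depths of 513.5 and 469.

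Changes were also present within single classes without FTY720. Bcl2 was lower in the stem-like class (-1.95 ± 0.25), the exhausted-like class (-2.50 ± 0.29) and the cycling-like class (-3.03 ± 0.27), with adjusted p of 0.00304, 6.41e-05 and 0.000757 by edgeR. Klrg1 was higher in all 3 (2.13 ± 0.54, 3.52 ± 0.43 and 4.12 ± 0.28), and so was Il12rb2 (1.58 ± 0.15, 1.16 ± 0.18 and 1.40 ± 0.14). Stem-like cells of RT held more Il7r, the survival receptor for interleukin 7 (0.72 ± 0.19), and Pdcd1 (0.84 ± 0.20), and less Gzmb (-0.83 ± 0.14). In the exhausted-like class the transcription factor Lef1 was higher (1.90 ± 0.44) and so was Cxcr3 (1.44 ± 0.26). These genes were chosen after their values were seen. In all, 80 of 281 genes passed in the stem-like class, 117 of 309 in the exhausted-like class, 114 of 287 in the cycling-like class and 38 of 307 in macrophage-like cells. Without RT replicate 1 these counts were 33, 0, 10 and 1, and in macrophage-like cells they were 85 without RT replicate 2 and 0 without either UNTR library. In the exhausted-like class, cluster 0 held 59.8% of the RT cells and cluster 4 held 68.3% of the UNTR cells.

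The second comparison asks what differed after irradiation in mice given FTY720. Cycling-like cells were 27.79% ± 0.21 (SD, n = 2) in RT_FTY and 1.71% ± 1.64 in UNTR_FTY at Leiden resolution 1.0, where cluster 2, which also expressed Mki67 and Top2a, stayed unnamed and held 8.28% and 5.59% of the UNTR_FTY libraries and 3.62% and 0.69% of the RT_FTY libraries. At resolution 0.5 cycling-like cells were 30.30% ± 0.72 and 7.82% ± 0.12, a smaller ratio with the same direction. Macrophage-like cells were 5.46% ± 2.90 and 27.72% ± 8.30. Stem-like cells were 6.72% ± 0.28 and 8.41% ± 5.85, and exhausted-like cells 8.93% ± 0.52 and 11.94% ± 14.05, so neither difference exceeded the spread between libraries. The exhausted-like share rests on the naming: cluster 0 (4110 RT_FTY and 146 UNTR_FTY cells) and cluster 13 (38 and 2493) stayed unnamed. Both had more Pdcd1 (670.2 and 819.1 CPM) than the exhausted-like clusters 5 and 7 (458.6 and 544.6). Their Gzmb levels were lower (1997.1 and 543.3 CPM, against 3543.6 and 2353.0). Most UNTR_FTY cells of cluster 13 came from replicate 1, and most of those of cluster 7 from replicate 2. The exhausted-like class held 126 cells in UNTR_FTY replicate 1 and 1782 in replicate 2. Libraries were clustered without integration, so among UNTR_FTY cells this split went with the library. Without UNTR_FTY replicate 2, the difference (share of cells with FTY720: stem-like CD8 T) was -5.83 percentage points, and without UNTR_FTY replicate 1 it was 2.44, against -1.69 with all libraries. Of T cells alone, stem-like cells were 7.26% ± 0.01 and 14.49% ± 6.05, with both RT_FTY libraries lower. The exact permutation p was 0.333, the smallest possible, for the cycling-like and macrophage-like shares and 1.0 for the stem-like and exhausted-like shares of all cells. With arrangements within each run over both experiments, the exact p was 0.056, the smallest possible, for macrophage-like cells. It was 0.111 for cycling-like, 0.167 for stem-like and 0.389 for exhausted-like cells. Among T cells these last 3 were 0.111, 0.056 and 0.889.

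In T cell clusters with FTY720, Bcl2 had a log2 fold change of -2.63 ± 0.19 (SE, n = 2) and Xcl1 of -2.40 ± 0.23, with both RT_FTY libraries below both UNTR_FTY libraries. Klrg1 had a value of 1.90 ± 0.24 and Ccr7 of -2.25 ± 0.31. None of these passed in edgeR (adjusted p = 0.385 for each). With the GC content trend of each library, strong in UNTR_FTY replicate 1, taken out, Bcl2 was at -2.78 ± 0.22, Xcl1 at -2.51 ± 0.23, Klrg1 at 1.87 ± 0.25 and Ccr7 at -2.07 ± 0.22, and the gene lists were not corrected for it. Mki67, a marker of dividing cells, had a value of 1.06 ± 0.35, and Tcf7 of -0.56 ± 0.29. Over all cells edgeR called 0 of 22542 genes, with 6194 at an unadjusted p under 0.05, while DESeq2 called 3964. In T cell clusters edgeR called 0 of 19681, with 2169 at an unadjusted p under 0.05, and DESeq2 called 481. Without replicate 1 or replicate 2 of UNTR_FTY, edgeR called 9075 and 9612 genes over all cells, and 4496 and 8770 in T cell clusters. Without replicate 1 or replicate 2 of RT_FTY it called 563 and 3 over all cells.

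As a group, mitosis genes lay higher in RT_FTY T cells: all 20 were above in both libraries, with a median log2 fold change of 1.04, and 12 passed as higher adjusted over the list alone against 0 over all genes. Ube2c (1.09 ± 0.17) and Ccnb2 (0.93 ± 0.18) are examples. The camera adjusted p was 5.4e-14, and with an estimated correlation the adjusted p = 0.416. For DNA replication genes 18 of 20 were above in both libraries, and 0 passed adjusted over the list alone. Their camera adjusted p was 1.7e-06, with an adjusted p = 0.416 under an estimated correlation. Glycolysis and hypoxia genes lay lower, 8 of 16 adjusted over the list alone, among them Egln3 (-2.28 ± 0.28) and P4ha1 (-0.93 ± 0.17), at a camera adjusted p of 1.29e-06 and an adjusted p = 0.416 with an estimated correlation. Exhausted CD8 T genes passed over all cells (camera adjusted p = 4.47e-07, and adjusted p = 0.277 with an estimated correlation) and not in T cell clusters (adjusted p = 0.973, with a median of -0.02). Macrophage genes were lower in T cell clusters too, with a median of -1.52 and 10 of 12 below in both libraries. Their camera adjusted p was 1.7e-06, and with an estimated correlation the adjusted p = 0.416. Fibroblast and tumor genes were lower with a median of -2.39, 4 of 7 adjusted over the list alone (camera adjusted p = 5.33e-05, and adjusted p = 0.416 with an estimated correlation).

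Within the exhausted-like class with FTY720, 216 of 14380 genes passed, 87 higher and 129 lower. The class held 126 cells in UNTR_FTY replicate 1 and 1782 in replicate 2, so most of its UNTR_FTY cells came from replicate 2. In RT_FTY replicates 1 and 2 it held 622 and 740 cells. Bcl2 fell by 3.11 ± 0.23 on the log2 scale (edgeR adjusted p = 0.0415) and Lef1 rose by 1.56 ± 0.22 (adjusted p = 0.047), as in that class without FTY720. Col6a1 (-4.82 ± 0.62) and Col3a1 (-4.14 ± 0.47), which encode collagen chains, fell as well. In UNTR_FTY more of the cells were in cluster 17, led by H19 and Col6a1 (3.11% and 16.01%, against 0.6% and 0.13% in RT_FTY), so RNA carried over from such cells is not excluded for these genes. These genes were chosen after their values were seen. Different clusters held the class in the 2 groups, cluster 5 for 86.3% of the RT_FTY cells and cluster 7 for 94.7% of the UNTR_FTY cells, and the count was 25 without RT_FTY replicate 2 and 5423 and 4229 without UNTR_FTY replicates 1 and 2. In the stem-like class edgeR called 0 of 11771 genes (1455 at an unadjusted p under 0.05, and 74 by DESeq2), with values of -1.76 ± 0.44 for Bcl2 and 2.45 ± 0.50 for Klrg1. Its cluster 3 held 80% of the RT_FTY cells and 54.0% of the UNTR_FTY cells, and without UNTR_FTY replicates 1 and 2 the count was 1391 and 4608. It also called 0 of 9047 genes in interferon-response-like cells (694 unadjusted, 14 by DESeq2) and 0 of 14542 in macrophage-like cells (1490 unadjusted, 283 by DESeq2), of which cluster 19 held 33.2% in UNTR_FTY and 0.1% in RT_FTY. Clusters 19 and 9 held 1364 and 2748 UNTR_FTY cells, close to the 1376 and 2736 macrophage-like cells of UNTR_FTY replicates 1 and 2. This split may therefore follow the library and not the treatment. Cycling-like cells as named at resolution 1.0 were too few in UNTR_FTY replicate 1 for this test, and those of resolution 0.5 were not tested.

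Antibody counts of the FTY720 run were read within each library, since their depth differed between libraries. The share of antibody counts from Ly-108, the protein of Slamf6, was 2.62, 3.71, 8.11 and 3.5 times as high in stem-like as in exhausted-like cells in RT_FTY replicates 1 and 2 and UNTR_FTY replicates 1 and 2. The ratio of 8.11 rests on 21 Ly-108 counts from 126 exhausted-like cells. CD366 (TIM-3) went the other way, with ratios of 0.36, 0.28, 0.25 and 0.29.

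Over both experiments, with the run as a term, Bcl2 was lower in T cell clusters (-2.67 ± 0.19, edgeR adjusted p = 4.45e-05) and Klrg1 higher (2.80 ± 0.43, adjusted p = 0.00245). Ccr7 (-1.92 ± 0.33) and Tcf7 (-1.03 ± 0.34) were lower, and Ccr2 (1.77 ± 0.31), Havcr2 (1.32 ± 0.35) and Mki67 (1.05 ± 0.22) higher. Of these, Bcl2, Ccr7, Tcf7 and Mki67 were carried over from the single experiments after their values were seen. Without RT_FTY replicate 2 Havcr2 no longer passed (adjusted p = 0.0507). In these clusters 118 of 350 genes passed, 32 higher and 86 lower, and over all cells 239 of 359, 111 higher and 128 lower. Within T cell clusters the count was 66 without RT_FTY replicate 2 and 186 without UNTR_FTY replicate 1. Across the 337 genes tested in both runs, log2 fold changes in T cell clusters had a Pearson r of 0.811, a value across genes, which are not independent replicates. Of the 31 genes higher without FTY720 27 had the same sign with it, and of 81 lower genes 81 did. In 18 of the 31 both RT_FTY libraries lay above both UNTR_FTY libraries, and in 55 of the 81 both lay below. The lower genes include all 7 macrophage genes measured without FTY720, and macrophage-like cells were rarer after irradiation in both experiments. RNA carried over from other cells may thus add to this agreement, which is not a measure of T cells alone.

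**Figure D2:**
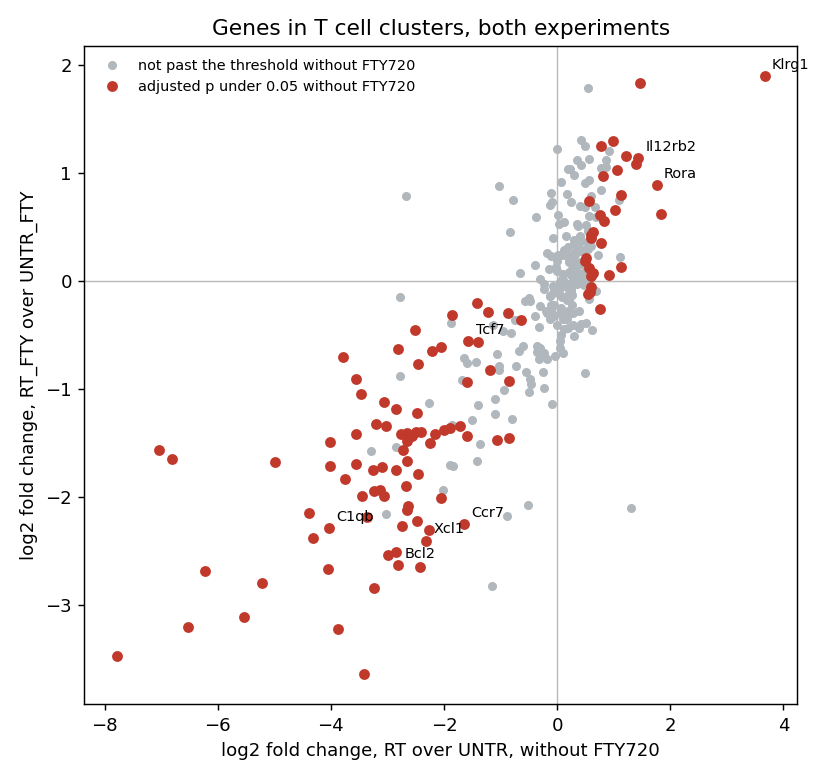
Each point is 1 of 337 genes in T cell clusters, with the log2 fold change of RT over UNTR without FTY720 on the x axis and of RT_FTY over UNTR_FTY on the y axis; red points passed an adjusted p of 0.05 without FTY720. Klrg1 lies high in both (3.67 and 1.90) and Bcl2 low in both (-2.82 and -2.63). The red points include macrophage genes such as C1qb.

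The test of whether the effect of irradiation differed between the experiments with and without FTY720 called 0 of 359 genes in edgeR over all cells, with 25 at an unadjusted p under 0.05 and 2 by DESeq2. The drug changed together with the assay and the sequencing run, so this test cannot single out FTY720. In simulated counts it recovered 2% of genes changed 2-fold and 30% of those changed 4-fold, so 0 calls do not show equal effects. In T cell clusters it called 0 of 350, with 27 unadjusted and 0 by DESeq2. Klrg1 had an interaction value of -1.78 ± 0.55 (adjusted p = 0.576), Tcf7 of 0.99 ± 0.59 (adjusted p = 0.73) and Bcl2 of 0.22 ± 0.38 (adjusted p = 0.87). Without UNTR_FTY replicate 2 the counts were 22 over all cells and 54 in T cell clusters, and without UNTR_FTY replicate 1 and UNTR replicate 1 they were 1 and 1.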

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

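No result met the rules for a closer look: the test for an outlying sample takes groups of at least 4 libraries, so these groups of 2 were not tested, no class and no named gene separated the RT and UNTR libraries in opposite directions in the 2 experiments, and the interaction test passed for 0 genes (25 at an unadjusted p under 0.05, and 2 by DESeq2).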

How the results depend on the processing

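Settings on T cell clusters, the highest doublet scores, T cells as denominator and GC content were chosen after seeing the data, and for changes below the cause was not tested. Among counts of genes, lists and classes, 144 alternatives stayed within 1.5 times the value reported and 81 did not. For named genes, 4121 kept their side of the threshold, 571 passed only under the alternative, 148 no longer passed and 4 reversed. With 2 libraries per group, leaving 1 out assumes that the lone library varies like the others. The labels do not say what the replicate numbers share: same-numbered libraries had correlated deviations of 0.299 without FTY720 and -0.18 with it, from 2 pairs each. With the replicate block 244, 0 and 223 genes were called without FTY720, with it and over both, against 205, 0 and 239 without the block.

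Without single libraries, counts over all cells ranged from 130 to 215 without FTY720, from 3 to 9612 with it and from 0 to 22 for the interaction, and in T cell clusters from 40 to 131, 0 to 8770 and 0 to 54, and from 66 to 186 over both experiments. Only T cell clusters gave 114 and 118 genes without FTY720 and over both. With FTY720, the DESeq2 test gave 3964 (481 in T cell clusters), no filter on low counts 1054, the stricter cell filter 1761 and the fit of all 8 libraries 153 of the 359 shared genes. The DESeq2 test gave 2 for the interaction.

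Within classes without FTY720 the ranges were 33 to 66 (stem-like), 0 to 118 (exhausted-like), 10 to 72 (cycling-like) and 0 to 85 (macrophage-like). At Leiden resolution 0.5 the exhausted-like count was 74 and the macrophage-like count 2, which was 1 with DESeq2 size factors and 87 with the replicate block. With FTY720 the ranges were 25 to 5423 (exhausted-like), 1 to 4608 (stem-like), 9 to 2773 (interferon-response-like) and 0 to 6113 (macrophage-like). The exhausted-like count was 331 with DESeq2 size factors, 521 with its test, 2034 without the low count filter, 393 with the replicate block, 373 with the GC correction and 411 at resolution 0.5. Without the low count filter the stem-like, interferon-response-like and macrophage-like counts were 697, 192 and 698, by DESeq2 74, 14 and 283, and with the block 106, 11 and 0. The interferon-response-like count was 7 with DESeq2 size factors and 4 with the GC correction.

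Lists called fell to 0 with an estimated correlation in both experiments, over all cells and in T cell clusters, and to 0 with fry in T cell clusters. Correlation between genes does not account for all of this. For dendritic cell genes over all cells with FTY720 the estimate was -0.019, below the preset 0.01. Their camera adjusted p still went from 2.44e-06 to 0.277, so this fall cannot show that correlation explains the list results. With an estimated correlation, camera also rests on the few residual degrees of freedom of so few libraries, which makes passing hard whatever the correlation. Without FTY720 the number ranged from 3 to 5 without single libraries (2 to 4 in T cell clusters, and 4 with the block). In T cell clusters with FTY720, the exhausted list no longer passed and had no clear direction (camera adjusted p of 0.973, median log2 fold change of -0.02). There the CD4 list turned to lower at a camera adjusted p of 0.000891.

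The number of classes that separated the groups was 3 at resolution 0.5 and 1 among T cells without FTY720, and 2 among T cells with it. The exhausted-like difference without FTY720 reversed to -3.04 at resolution 0.5 and -2.27 without cell cycle genes, and was 1.44 at resolution 1.5, where the stem-like one was -0.53. Other lineages differed by -17.74 without the highest doublet scores. With FTY720 the cycling-like difference was 22.47 and 23.67 at resolutions 0.5 and 1.5, 31.33 without cell cycle genes and 24.57 without the highest doublet scores. Among T cells the exhausted-like and stem-like differences were -17.98 and -7.23, and the stem-like one among all cells (share of cells with FTY720: stem-like CD8 T) ranged from -5.83 to 2.44 without single libraries. The -17.98 rests on UNTR_FTY replicate 2, where 1782 of 3407 T cells were exhausted-like, against 126 of 4209 in replicate 1. The RT_FTY libraries (622 of 6002 and 740 of 8241) lay between these. Gzmb reversed to -0.12 in T cell clusters without FTY720, and with FTY720 the sign turned with the library left out: Hspa5 was -0.66 without UNTR_FTY replicate 1 and 0.62 without replicate 2, and in T cell clusters Mcm6 was 0.32 and -0.24 and Trgc2 -1.5 and 0.51. Gene tests within cycling-like cells of the FTY720 run and the FTY720 effect itself were not run.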

Other observations

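The tests of splits, of sequencing depth, of RNA from other cells, of the share of stem-like cells and of cell types in the sums over all cells were written after their results were seen, and so was the rule for T cell clusters that most tests use. Over both experiments, only splits of the 8 libraries with 2 libraries of each run in each arm are comparable, and these are 18, of which 1, the real one, gave as many genes. That is too few for a share under 0.05. The real split gave 239 genes over all cells and 118 in T cell clusters, and the highest of the others 0.

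Tcf7 and Ccr7 were lower after RT in T cell clusters without FTY720. Depth per cell is argued against, since T cells had a higher median depth in both RT libraries than in both UNTR libraries. Thinning could therefore hardly close the gap, and after it the lower UNTR share was at least 1.68 times the higher RT share for both genes. RNA from other cells is argued against for these 2 genes as the whole cause, since at the median level that the leading genes of each other cluster allow in UNTR T cells, those clusters together could bring at most 14.9% of the gap to RT (Ccr7 in UNTR replicate 2), by a test written after an earlier one on detection shares had been seen. A lower share of stem-like cells cannot be told apart from a change within cells: without stem-like and naive-like cells as named at resolution 1.5, the log2 fold changes were -0.98 ± 0.34 for Tcf7 and -1.09 ± 0.42 for Ccr7, against -1.56 and -1.64 with them, and neither passed (adjusted p = 0.0782 and 0.0992 by edgeR). Without the stem-like cells of resolution 1.0 they were -1.28 ± 0.39 (adjusted p = 0.0628) and -1.98 ± 0.45 (adjusted p = 0.032), so both explanations may contribute.

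Of the 86 genes higher after RT in the sums over all cells without FTY720, 27 still passed in T cell clusters, and their median log2 fold change went from 1.31 to 0.50, consistent with a lower share of other cell types in RT for most of them. For the 31 genes higher in T cell clusters this explanation cannot be told apart: their median within the exhausted-like class was 0.67, against 0.78, but that class is part of the cells in which they were chosen and keeps any RNA carried over from other cells.

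UNTR_FTY replicate 1 had a mitochondrial share far below the other 3 libraries of its run. Loss of cytoplasm failed its prediction: ribosomal protein genes took 1.53 times the lowest share of the others. Neat1, a nuclear RNA, was the lowest of the 4 libraries (52.7 CPM against 54.1 to 99.9), although Malat1, another, was the highest (2594.6 CPM against 1216.8 to 2001.8). These shares were not corrected for the GC content trend of this library, so they cannot decide on this explanation. Different handling of mitochondrial genes cannot be told apart, since the ratio varied 5.75-fold between these genes, between the bounds set for it. GC content bias may contribute: nuclear genes in the GC range of the mitochondrial genes lay at -1.01 on the log2 scale relative to all nuclear genes, just past the bound of 1, while mitochondrial genes lay at -3.48, so it covers the direction and not the whole size. No biological explanation was tested.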
